A study of Mus musculus with 6 samples.

How the data were processed

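RNA was sequenced from 6 samples of sorted mouse alveolar macrophages, 3 cultured with solvent (0.1 M NaOH is the stated solvent of hematin) and 3 with 40 μM hematin for 2 h. Per the labels, each sample was sorted from the pooled lavage of 3 mice, libraries were made from 1 μg of RNA with a TruSeq kit, and single-end reads of 50 nt were produced. The series' design text calls the control cells untreated, while the treatment protocol describes them as given the solvent. The treatment label of each sample set its group. Whether a mock and a hematin sample could share a pool of mice is not given in the sources used here, and the numbers in the labels differ between groups, so no pairing was used. The numbers 1 to 3 used here follow the order of deposit in each group and only name a sample. Each sample is a pool, so p-values measure the spread between pooled samples and not between single mice. Where a mock and a hematin sample shared a pool, the test would ignore that pairing. Where 2 samples of a group shared a pool, their spread would not measure that between pools.

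Per the submitters' processing notes, bcl2fastq 2.15.0, Bowtie 1.0.1, RSEM 1.2.15 and SAMtools 0.1.19 were used with the mouse build mm9. Each deposited table held, per the file headers, an expected count for each gene model, which is an estimated number of reads that RSEM divides among models and that need not be whole. It also held an FPKM value made by the authors, which scales that count by model length and by library size. Between 35.8 and 39.2% of nonzero expected counts were whole within 0.005. Model length implied by count, FPKM and library total differed by less than 1% between libraries in 100% of comparisons of 1-transcript models. The FPKM values therefore follow plain library totals, without the TMM scaling used for CPM below. Whether counting used strand is not given in the sources used here, so a model that overlaps another or has a near-identical copy elsewhere has an uncertain count.

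Models were named by UCSC-style transcript identifiers, and 58.0% of the 28427 had 1 transcript. The files do not pair identifiers with gene names, and 0 of 55116 identifiers matched the reference tables used here. No gene name, function or coordinate is therefore given, and the 30 gene lists fixed before the data were examined, markers of other cell types among them, were not tested. The rule for named genes was also fixed then. It took the 10 largest rises and 10 largest falls past the threshold with non-overlapping groups and at least 5 CPM in the higher group, list members, and 3 genes by symbol, one of them the transporter gene in the series' title. Without names it was reduced to the first 2 models in each direction, from 82 eligible rises and 14 eligible falls. The exclusion of unnamed gene models that the rule asked for could not be applied.

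Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Models were kept by filterByExpr, libraries were scaled by TMM (factors 1.06, 1.03 and 1.12 in mock and 0.999, 0.899 and 0.910 in hematin samples), and groups were compared with glmQLFit and glmQLFTest without covariates. The Benjamini-Hochberg threshold was 0.05, and a second count required a 2-fold change. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-scaled, shares of the called sets are percents of the counts of tested models, other shares are percents of all counts, and each library's total is its depth. The common biological coefficient of variation was 18.7%, and at an unadjusted p of 0.05 the fit passed 1781 models, or 14.1%.

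The fit was tested on simulated counts for this comparison in 5 runs of up to 12403 tested models, with 200 changed in each. The changed models were drawn from those of at least 1 CPM, so recovery below that level was not measured. With the trended spread, 26.4% of 1.5-fold and 74.2% of 2-fold changes were recovered and 5.63% of calls were false. With each model's own estimated spread, 21% and 71% were recovered and 8% of calls were false, above the nominal 5%. Counts were drawn independently for each model, so library differences common to many models were left out. Recovery and false calls in the real libraries may therefore differ from these values.

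Alternatives fixed before the data were examined were median-of-ratios and upper-quartile scaling, no filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom and limma-trend on log2(FPKM + 1) with limma 3.58.1, unrounded expected counts, and each library left out in turn. A fit without mock 3 and hematin 1, a fit with 1 surrogate variable from sva 3.50.0 and scaling by plain library totals were added after the data were seen. Similarity was measured by Spearman correlation of log2(CPM + 1), with Pearson correlation and a pseudocount of 0.25 as alternatives.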

Results

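Gene expression was measured by RNA sequencing in mouse alveolar macrophages, the resident phagocytes of the airspaces, after a short culture with or without hematin. Hematin is the hydroxide form of oxidised heme, the iron porphyrin that hemoglobin carries. The cells came from lung lavage of C57BL/6J mice, were sorted for the surface proteins CD11c and Siglec-F, and each sample pooled the lavage of 3 mice. Per the treatment protocol, mock samples (n = 3) received the solvent, though the series' design text calls the control cells untreated. Hematin samples (n = 3) received 40 μM hematin, and both cultures lasted 2 h. The deposited tables held 28427 gene models, each named by 1 or more transcript identifiers and not by a gene symbol. The files do not pair these identifiers with gene names, so genes are described here by direction, size of change and abundance.

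The libraries held 36839446, 27628483 and 22748791 expected counts in mock samples 1 to 3 and 29091943, 28037159 and 29828872 in hematin samples 1 to 3. The mean was 29072240 ± 7155416 in the mock group and 28985991 ± 900543 in the hematin group (SD, n = 3 each). Between 15775 and 16530 gene models had a count in a library, and 9673 had none in any of the 6. At these depths 3 counts correspond to between 0.0814 and 0.132 CPM, the count scaled to library size, and this floor covers counting error only. No sample repeated another, since the counts of samples of 1 group differed by a chi-square per degree of freedom of 18.3 to 94.8.

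The 6 profiles were close to each other, and the whole-profile correlation did not separate the treatments. Spearman correlations of log2(CPM + 1) had a median of 0.962 over the 6 pairs within a group (0.960 to 0.963) and of 0.962 over the 9 pairs between groups (0.958 to 0.965). They were taken across all 28427 gene models, of which 9673 had no count in any library. The chi-square per degree of freedom differed more, with medians of 57.2 within and 117 between groups. Its ranges overlapped, at 18.3 to 94.8 and 72.7 to 149.8. The first principal component, with 37.0% of the variance, set mock 3 (27.1) and hematin 1 (15.2) apart from the other 4 libraries, which lay between -18.5 and -2.08. The second component, with 27.6% of the variance, placed the mock samples at 12.1, 18.2 and 6.39 and the hematin samples at -21.0, -15.7 and -0.051.

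**Figure D1:**
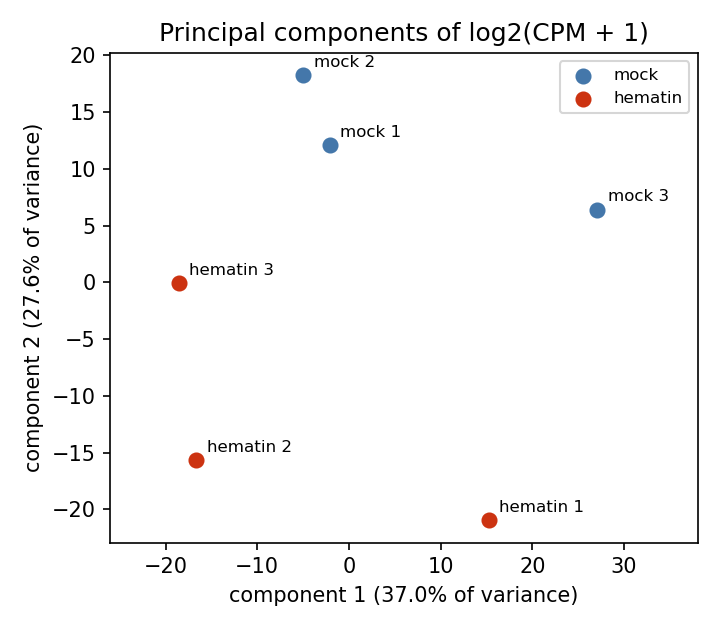
Principal components of log2(CPM + 1), component 1 on the horizontal axis (37.0% of variance) and component 2 on the vertical axis (27.6%), 1 point per library, mock in blue and hematin in red. Mock 3 and hematin 1 lie to the right of the other 4 libraries, and the 3 mock samples lie above the 3 hematin samples.

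The study's comparison asked how 2 h of heme exposure changes transcription in these cells. Among 12595 gene models tested, 100 differed between hematin and mock, of which 86 rose and 14 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Before adjustment the same fit gave 884 gene models higher and 897 lower at a p under 0.05. That balance depends on the zero point set by TMM, which placed the median log2 fold change of all tested gene models at -0.0086. A change of at least 2-fold was found for 42 of the 100, of which 40 rose and 2 fell. The gene models that rose had a median log2 fold change of 0.97, or 1.95-fold, with a range of 0.46 to 3.43. Those that fell had a median of -0.69, or 0.618 of the mock level, with a range of -1.28 to -0.47. All 100 had the 3 hematin values on 1 side of the 3 mock values. Over all tested gene models this held for 20.6%, with 1228 higher and 1363 lower. A random order of the 6 values would give 10% on average over splits, but gene models are not independent. At an unadjusted p under 0.05 the real split of the libraries passed 1781 gene models. Splits that mixed the treatments passed 70 to 1370, the most with mock 1, mock 3 and hematin 1 against the rest. The excess over 10% is therefore not assigned to hematin alone. With plain library totals, a scaling added after the data were seen, edgeR passed 215 gene models, 68 higher and 147 lower, and at least 2-fold 27 higher and 13 lower; this scaling moved the median log2 fold change of all tested gene models from -0.0086 to -0.20. With limma-trend on log2(FPKM + 1), which changes the test as well as the values, 155 passed, 64 higher and 91 lower, and at least 2-fold 24 higher and 5 lower, with a median of -0.15. FPKM also follows plain library totals, so this fit is not independent of the one before it. With 1 library left out, and so fewer samples in its group, there were 13 calls without mock 1, 21 without mock 2, 91 without mock 3, 16 without hematin 2, 41 without hematin 3 and 211 without hematin 1. Leaving out both mock 3 and hematin 1, a choice made after the data were seen, gave 243 calls, of which 201 rose and 42 fell. With all 6 libraries, DESeq2 gave 363 calls, of which 283 rose and 80 fell, and edgeR with 1 surrogate variable, also added after the data were seen, gave 382, of which 260 rose and 122 fell.

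The gene models that rose took a larger part of the library after hematin. Together the 86 held 2.22 ± 0.0954% of the tested counts in mock samples and 5.81 ± 0.465% in hematin samples (SD, n = 3). A large part of this increase lay in 1 of the 86, uc009mhc.2. That gene model alone went from 0.593 ± 0.0368% to 2.44 ± 0.170% of all counts (SD, n = 3). The 14 that fell held 0.0910 ± 0.00102% and 0.0497 ± 0.00268% (SD, n = 3). Both sets were chosen on these libraries, so the shares describe the calls and do not test them. The 50 most abundant gene models of each library took 21.8 ± 0.120% of the counts in mock and 26.7 ± 1.2% in hematin samples (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 samples can give).

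The rises reached from scarce to the most abundant transcripts, while the falls that edgeR called lay in the middle of the range. Gene models with a mean under 10 CPM gave 9 rises and 0 falls among 5426 tested by edgeR. Those from 10 to under 100 CPM gave 34 rises and 12 falls among 5316, and those from 100 to under 1000 CPM gave 37 rises and 2 falls among 1727. Of the 126 at 1000 CPM or more, 6 rose and 0 fell. Falls were 0.111% of all tested gene models, so 0 among 126 does not set this tier apart. In the tiers with 0 falls, edgeR gave 344 and 2 lower gene models at an unadjusted p under 0.05, and the falls called were 17 and 1 by DESeq2, 0 and 0 by limma-voom and 14 and 1 by limma-trend on FPKM. The median abundance was 104 CPM for gene models that rose and 43.9 CPM for those that fell. In data simulated for this comparison, the changed gene models were drawn from those of at least 1 CPM. With the trended spread, a 2-fold change was recovered for 34.6% of them under 10 CPM, 95% from 10 to under 100 CPM and 100% at 100 CPM or more. Under 10 CPM it was 27.4% with each model's own spread. Simulated 2-fold changes from 1 to under 10 CPM were therefore mostly missed, and changes under 1 CPM were not simulated.

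**Figure D2:**
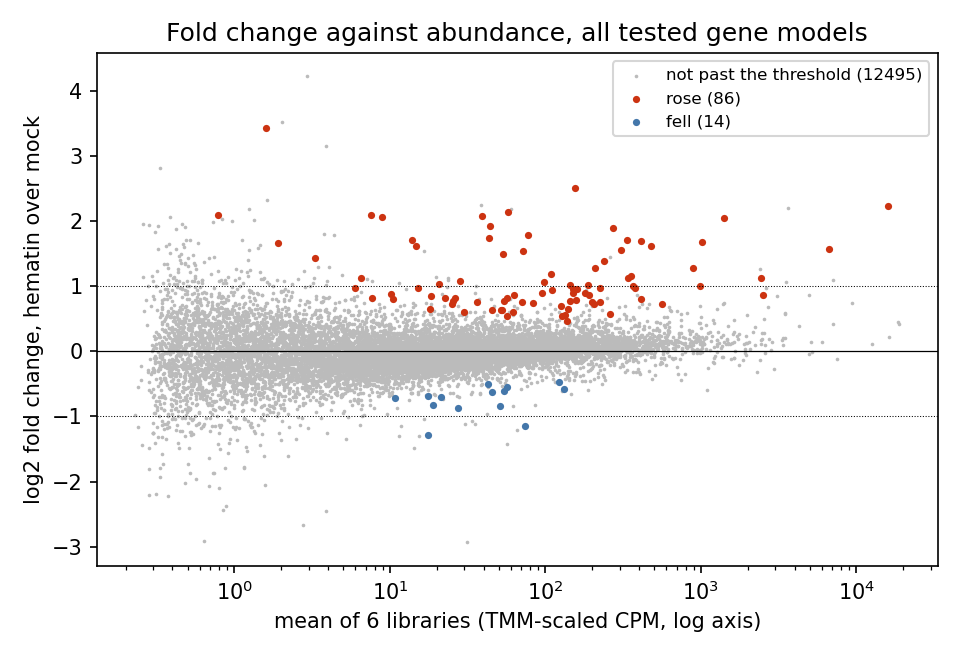
Log2 fold change of hematin over mock against the mean of the 6 libraries (TMM-scaled CPM, log axis), 1 point per tested gene model, with dotted lines at 2-fold. The 86 gene models that rose (red) extend above 1000 CPM, and the 14 that fell (blue) lie between 10 and 1000 CPM; with plain library totals the split was 68 higher and 147 lower.

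Among the called gene models with at least 5 CPM in the higher group, the largest rise was that of uc007cxj.2,uc007cxk.1, a model with 2 transcripts. Its level went from 46.5 ± 8.47 CPM in mock to 265 ± 33.7 CPM in hematin samples (SD, n = 3), a 5.70-fold increase. The log2 fold change was 2.51 ± 0.15 (SE; edgeR adjusted p = 0.000601), on 1051 to 7764 counts per library. In the authors' FPKM the same model went from 37.3 ± 6.54 to 187 ± 25.1 (SD, n = 3). It passed the threshold in all 17 alternative fits. The gene model next to it in identifier order also rose, by 0.73 on the log2 scale, and reads divided between neighbouring models were not excluded.

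Among the same called gene models, the second largest rise was that of uc009mhc.2, a model with 1 transcript that was already abundant without treatment. It rose 4.72-fold, from 5557 ± 560 to 26225 ± 3247 CPM (SD, n = 3), with a log2 fold change of 2.24 ± 0.21 (SE; edgeR adjusted p = 0.00303). Its share of all counts went from 0.593 ± 0.0368% to 2.44 ± 0.170% (SD, n = 3), which moved it from rank 9 by mean abundance in the mock group to rank 1 in the hematin group. Its FPKM went from 3780 ± 234 to 15555 ± 1081 (SD, n = 3). Without mock 1 the fold was kept at 2.24 on the log2 scale, but edgeR's adjusted p was 0.0562; over the 17 alternatives, DESeq2 and limma included, the adjusted p ranged from 1.09e-64 to 0.0562.

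Both called falls of at least 2-fold were in gene models of moderate abundance. The model uc007cne.1,uc007cnf.1 fell from 24.8 ± 4.50 to 10.2 ± 0.496 CPM (SD, n = 3), a log2 fold change of -1.28 ± 0.15 (SE; edgeR adjusted p = 0.00713). Its FPKM fell from 8.92 ± 1.43 to 3.21 ± 0.286 (SD, n = 3). The model uc007ctt.1 fell from 102 ± 15 to 46.0 ± 7.18 CPM (SD, n = 3), a log2 fold change of -1.15 ± 0.14 (SE; edgeR adjusted p = 0.0105), and its FPKM fell from 36.1 ± 4.19 to 14.2 ± 1.48 (SD, n = 3). Both calls were lost in some fits with 1 library fewer, at similar folds. The first was lost without mock 2 (edgeR adjusted p = 0.0518) and without hematin 2 (0.0613), at a log2 fold change of -1.28 in each, with a range of adjusted p of 5.73e-11 to 0.0613 over the 17 alternatives. The second was lost without mock 1 (0.0562), mock 2 (0.0546) and hematin 2 (0.0621), at -1.21, -1.02 and -1.22, with a range of 9.03e-11 to 0.0621.

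**Figure D3:**
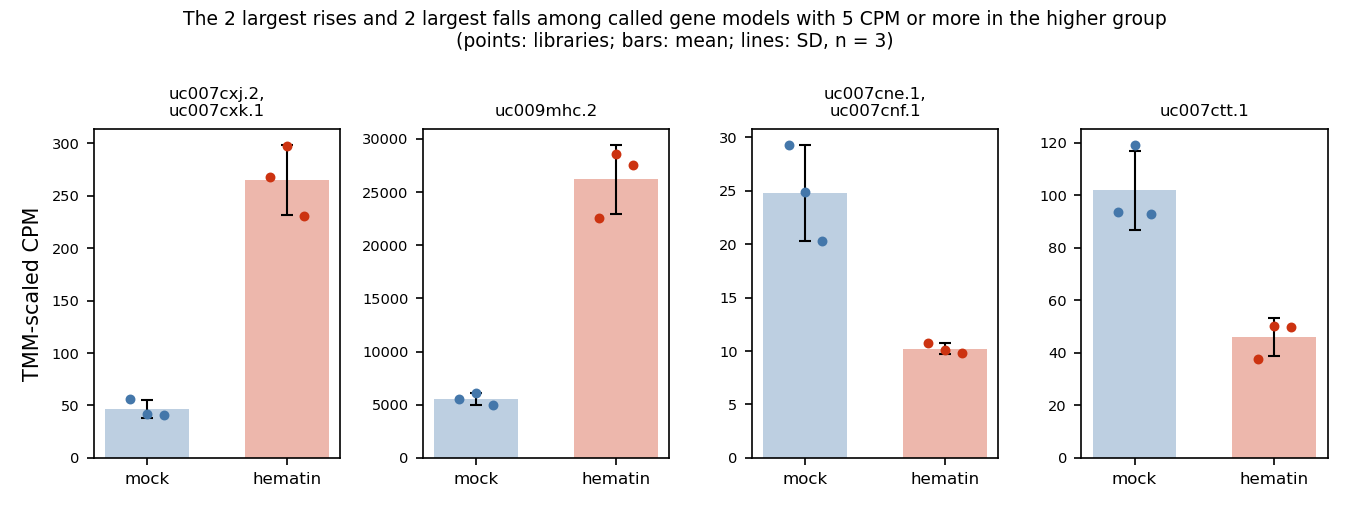
Level in TMM-scaled CPM (vertical axes, from 0) of the 4 named gene models in mock (blue) and hematin (red) samples; points are libraries, bars group means and lines SD (n = 3). In each panel the 3 hematin samples lie on 1 side of the 3 mock samples, above them for uc007cxj.2,uc007cxk.1 and uc009mhc.2 and below them for uc007cne.1,uc007cnf.1 and uc007ctt.1.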

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

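The fits without mock 3 and hematin 1, with 1 surrogate variable and with plain library totals were chosen after the data were seen. All 100 calls kept their direction in the 17 alternative fits, which tests little, because the hematin and mock values of each call did not overlap. The number of calls stayed within 1.5 times under median-of-ratios (105) and upper-quartile scaling (112), no filter (149), a filter of 1 CPM (120), limma-voom (100) and unrounded counts (100). DESeq2 called 363 (283 rose, 80 fell), 70 of them 2-fold (63 rose, 7 fell). The limma-trend fit on FPKM, which changes both test and values, gave 155 calls (91 fell), with 24 rises and 5 falls of 2-fold, and plain totals gave 215 (147 fell), 40 of them 2-fold (27 rose, 13 fell). Both of these fits lack TMM scaling. Without mock 3 and hematin 1 there were 243 calls (201 rose, 42 fell), 78 of them 2-fold (66 rose, 12 fell). With the surrogate variable there were 382 (260 rose, 122 fell), 65 of them 2-fold (14 fell). Without a filter 23 fell, 4 of them 2-fold. Leaving out 1 library gave 13 to 211 calls, 12 to 180 rises and 0 to 31 falls; of 2-fold changes there were 12 to 62, with 11 to 58 rises and 0 to 7 falls. The 0 falls, without mock 2 and without hematin 2, stood beside 595 and 539 at an unadjusted p under 0.05 by edgeR. In these fits 1 group had fewer samples, and 11 of the 100 calls passed in all 6. For the other alternatives the cause was not tested. Median Pearson correlation was 0.994852 within and 0.994303 between groups, and a pseudocount of 0.25 left the Spearman medians at 0.962. The 30 gene lists could not be tested under any setting, because the identifiers are not paired with names. No paired analysis was possible because the labels share no sample number between groups, and the numbers 1 to 3 follow the order of deposit.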

Other observations

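The test of equal recovery of falls and rises, the test of 1 added cell population and the comparison of shifts between abundance tiers were chosen only after the results they bear on were seen, as were the fits without mock 3 and hematin 1, with 1 surrogate variable and with plain library totals. Of the 10 splits of the 6 samples into 3 and 3, 1 gave as many calls as the real split, which is the real split itself, both for all calls (100, highest other split 3) and for 2-fold calls (42, highest other split 3). With 10 splits no share under 0.05 can be reached. At an unadjusted p under 0.05 by edgeR, the real split passed 1781 gene models and the other splits 70 to 1370.

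Abundant gene models had higher fold changes than scarce ones, but this was not resolved between libraries. The median log2 fold change was -0.058 under 10 CPM, -0.024 from 10 to under 100 CPM, 0.081 from 100 to under 1000 CPM and 0.17 at 1000 CPM or more. Plain library totals lowered each tier by a similar amount, to -0.25, -0.22, -0.11 and -0.028, so the top tier exceeded the lowest by 0.23 with TMM and 0.22 with plain totals. This difference was 0.13 without mock 3 and 0.34 without hematin 1. Comparing the tier medians of single libraries gave two-sided exact permutation p-values of 0.5, 0.1, 0.3 and 0.2, or 0.5, 0.4, 0.4 and 0.4 after Benjamini-Hochberg adjustment over the 4 tiers; the smallest possible was 0.1.

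Most changed gene models rose (86 of 100), and 86.7% and 88.4% of calls rose with median-of-ratios and upper-quartile scaling. The share was 31.6% with plain library totals, but that scaling lowered every abundance tier by about the same amount (tier shifts within 0.0055 of each other on the log2 scale), which by itself moves calls toward falls, and 67.5% of its 2-fold calls rose. The libraries mock 3 and hematin 1 are argued against as the whole source, since 82.7% of 243 calls rose without them, though the share was lower, 68.1% of 382 calls, with a surrogate variable that is highest in these 2 libraries. Simulated 2-fold falls were recovered 0.912 times as often as rises (0.839 with each model's own spread), while the 2-fold calls were 2 falls and 40 rises. At 1.5-fold, 24.4% of falls and 28.4% of rises were recovered with the trended spread. In the simulated counts, falls of these sizes were thus recovered only somewhat less often than rises. Those counts were drawn independently for each gene model, without differences between libraries such as those of mock 3 and hematin 1. The simulation therefore does not decide whether poorer detection of falls was the source. Smaller falls were not simulated, so their poorer detection also stays open. At an unadjusted p under 0.05, 897 fell and 884 rose, but this balance depends on the zero point that TMM set and decides nothing. A real excess of rises and the choice of scaling cannot be told apart, because the files hold no measure of RNA per cell that would set the zero point.

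On the log2(CPM + 1) scale, 46 gene models were more than 2-fold higher in both mock 3 and hematin 1 than in each of the other 4 libraries, against at most 3 for any other pair of libraries, and 0 of the 46 passed between treatments by edgeR, DESeq2, limma-voom or limma-trend on FPKM (0 at an unadjusted p under 0.05 by each), a result that choosing them in 1 library of each group favours. They made up 0.226% of the counts in mock 3 and 0.165% in hematin 1, against 0.0382 to 0.0509% elsewhere. An exchange of these samples between the groups is argued against, since they ordered 91.3% of the 242 gene models compared as the groups did, of 243 called in the other 4 libraries. A single added cell population of the same make-up stays open: log2 ratios of hematin 1 to mock 3 varied 2.27 times as much over these gene models as over abundance-matched ones (SD 0.799 against 0.352), but models chosen for differing between libraries can be more variable in general, and no other pair of libraries gave enough of them to compare. Several populations, or a pool of mice or a day that these samples may have shared, were not tested.

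The gene model uc008qvw.2, chosen after its values were seen, followed the same libraries. It held 1.23, 1.02 and 3.00% of the counts in mock samples 1 to 3 and 3.44, 1.53 and 1.22% in hematin samples 1 to 3, and it did not pass the test between treatments (log2 fold change 0.43, edgeR adjusted p = 0.719).

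In identifier order there were 5 adjacent pairs among the 100 changed gene models against 0.784 expected (one-sided permutation p = 0.00119, 100000 permutations), and both members of each of the 5 moved in the same direction. The likeness of neighbours was not particular to the calls: over all tested gene models, neighbours' fold changes had a Spearman correlation of 0.0952 across genes, which are not independent replicates, against at most 0.0363 in 1000 shuffled orders, and the expected 0.784 pairs do not allow for it. Reads shared between neighbouring gene models could give such pairs, and the test of this asked for a member with whole counts in all 6 libraries and found 0 of 5 pairs with one, but 86.7% of the 90 called models outside pairs also had mostly fractional counts, a comparison added after the result was seen. Shared reads and joint regulation therefore cannot be told apart. Counting each pair once leaves 95 calls, and whether identifier order follows the chromosome was not tested here.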
